A study of Mus musculus with 8 samples.

How the data were processed

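Brain lysates of adult male mice were measured on 8 Affymetrix Mouse Gene 1.0 ST arrays, 4 labelled TNF-/- and 4 labelled TNF+/+, and each array stands for 1 biological replicate per the labels. The deposited table gives the authors' log2 signal of 35556 probe sets per array. The submitters' processing notes name GCOS, GCRMA and Partek, without versions or roles; the scale follows from the values, which run from 2.83 to 14.1, and the genome build is not given in the sources used here. Groups and replicate numbers came from the sample titles, and 0 columns of values were left unused. No 2 columns were identical. The values were used as deposited, with no further normalization and no filter, and all 35556 probe sets were tested because the annotation used marks no control probe sets.

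Probe sets were named through the platform annotation: 21789 pair with 1 gene symbol, 1621 with several and 12146 are not listed, so these last are unnamed here. Of those with 1 symbol, 21698 matched the RefSeq table of GRCm38.p6 by gene ID and 0 symbols changed. That table served for names, chromosomes and the order of 19856 genes, and none of its coordinates is printed. The 19938 genes with a symbol were each represented by the probe set with the highest mean over the 8 arrays; 999 genes had several probe sets.

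The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit with a term for genotype, eBayes with 2.52 prior degrees of freedom, two-sided, Benjamini-Hochberg over all probe sets). A call is an adjusted p under 0.05. Errors given as SE are limma's moderated standard errors, and differences are arrays labelled TNF-/- minus arrays labelled TNF+/+ on the log2 scale. SAM, which the series' design text names, was rebuilt in R with all 70 assignments of the 8 arrays, s0 by Tusher's method (0.0357), a share of unchanged probe sets of 79.4% and the lowest delta (1.40) with an estimated false discovery rate under 5%. Before the data were examined, 33 gene lists were fixed and tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg over the lists; camera with an estimated correlation, fry and an exact two-sided permutation test of list means were run beside it. Of the 33 lists 6 passed with the preset correlation, 0 with an estimated one (4 at an unadjusted p under 0.05) and 5 by fry, and 7 had an unadjusted exact p under 0.05. Fry asks whether a list's genes move one way on balance and does not set them against other genes. The 50 measured genes nearest to Tnf, 25 on each side, were set against all others with Fisher's exact test. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

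The named genes were fixed by a rule before the data were examined. They are Tnf; up to 12 higher and 12 lower genes with the largest change among those past the limma threshold with no overlap between groups; the 3 members of each list with the smallest p; those of the genes nearest to Tnf that passed; and further genes of interest fixed by name, of which 1 is not reported here. Of these 120 genes 10 were past the threshold with no overlap. Members that passed over their list alone are named beyond this rule, from values already seen.

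The limma, SAM and camera tests were tried on simulated data with the real arrays' means and spread. Among 35556 probe sets, limma recovered 50% of 100 probe sets changed by 0.5 and 85% of 100 changed by 1 on the log2 scale, and SAM 43% and 85%. Of the calls 8.78% were false for limma and 7.25% for SAM, above the nominal 5%. Camera called 0 of 660 unchanged lists in simulated tables with independent genes. In the real arrays the estimated correlation within the 6 called lists ran from -0.05 (blood cells) to 0.35 (respiratory chain). The simulation therefore does not give the rate of false calls for real lists. The trial of limma and SAM also drew its probe sets independently. Alternatives tried were other filters, scalings, variance models and array weights, the replicate number as a block, other SAM settings, other list tests, and leaving out each array in turn. The groups share replicate numbers, which nothing in the labels ties to a shared litter or day.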

Results

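Gene expression was profiled in brain lysates of adult male mice aged 2 to 4 months, to ask how a lack of the cytokine tumour necrosis factor (TNF) changes gene expression, in a study that also addressed monoamines, neurogenesis, cell composition and the blood-brain barrier. The labels name 4 biological replicates as TNF-/- and 4 as TNF+/+. RNA of each was hybridised to its own Affymetrix Mouse Gene 1.0 ST array, and each array gave a log2 signal for 35556 probe sets. Array medians lay between 5.03 and 5.11, and Pearson's r between arrays, across probe sets, lay between 0.9863 and 0.9934. The number of arrays, 4 per group, limits the precision of each comparison. The first principal component held 24% of the variance and set TNF+/+ arrays 3 and 4 apart, with scores of 22.05 and 37.22 against -4.29 or lower for the other 6 arrays. TNF+/+ array 1 had high signals of several genes of the cerebellum list. Its signal of Gabra6, a GABA receptor subunit of cerebellar granule cells, was 16-fold the mean of the other 7 arrays, and that of Cbln3 was 7.80-fold. Not all members followed: its signals of Calb1 and Pvalb were each 1.04-fold that mean. The mean of the cerebellum list was 6.49 in this array and 5.61 over the other 3 TNF+/+ arrays.

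Signal of the targeted gene went against the labels. Tnf signal was 5.92 ± 0.22 (SD, n = 4) in the arrays labelled TNF-/- and 4.53 ± 0.29 (SD, n = 4) in those labelled TNF+/+, a difference of 1.39 ± 0.16 (SE) on the log2 scale, or 2.62-fold (limma, adjusted p = 0.0278). Each of the 4 arrays labelled TNF-/- (5.67, 5.87, 5.92 and 6.21) lay above each of the 4 labelled TNF+/+ (4.48, 4.93, 4.24 and 4.47), and the exact two-sided permutation p was 0.0286, the smallest that 4 against 4 can give. One probe set pairs with Tnf alone. The labels give neither the allele nor the deleted part, and where the probes lie is not given in the sources used here; a probe set outside the deleted part checks nothing. Every direction below is therefore that of arrays as labelled. With 1 array left out, the adjusted p of Tnf ran from 0.0321 to 0.114 and passed in 1 of 8 cases.

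Beside Tnf, 6 named genes rose and 3 fell in the arrays labelled TNF-/-, against those labelled TNF+/+. Higher were Catspere2, which encodes a relative of sperm calcium channel subunits, by 1.14 ± 0.09 (SE), Lpl, which encodes lipoprotein lipase, by 1.14 ± 0.11, the microRNA gene Mir377 by 1.11 ± 0.11, and Glo1, which encodes the methylglyoxal-detoxifying enzyme glyoxalase 1, by 1.05 ± 0.11 on the log2 scale (limma, adjusted p = 0.0119, 0.0151, 0.0151 and 0.0196). Rgcc, a regulator of the cell cycle, rose by 0.85 ± 0.11, and Susd2, which encodes a membrane protein with a sushi domain, by 0.43 ± 0.05 (limma, adjusted p = 0.0473 and 0.0317). Cthrc1, which encodes a secreted protein with collagen repeats, fell by 1.49 on the log2 scale, from 6.85 ± 0.22 to 5.36 ± 0.25 (SD, n = 4; limma, adjusted p = 0.0151). Baalc, which encodes a cytoplasmic protein of brain and leukaemic cells, fell by 0.77 on the log2 scale, and Nnt, which encodes the mitochondrial nicotinamide nucleotide transhydrogenase, fell by 0.74 on the log2 scale (limma, adjusted p = 0.0332 and 0.0151). Baalc and Cthrc1 are neighbours on chromosome 15, so they may not be separate findings. Fzd6, the only measured gene between them, differed by -0.56 (limma, adjusted p = 0.151). With 1 array left out in turn, Catspere2 passed in 7 of 8 cases, Cthrc1 and Lpl in 4, Mir377 in 3, Glo1 and Nnt in 2 and Baalc in 1, and Rgcc and Susd2 in 0 (limma, adjusted p = 0.059 to 0.18 and 0.0745 to 0.134). A second probe set of Glo1 rose by 1.01 (limma, adjusted p = 0.0317). One further gene was picked after its values were seen: A930017M01Rik rose by 0.91 in 1 probe set (limma, adjusted p = 0.0438), while its brighter probe set differed by 0.53 (adjusted p = 0.142).

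**Figure D1:**
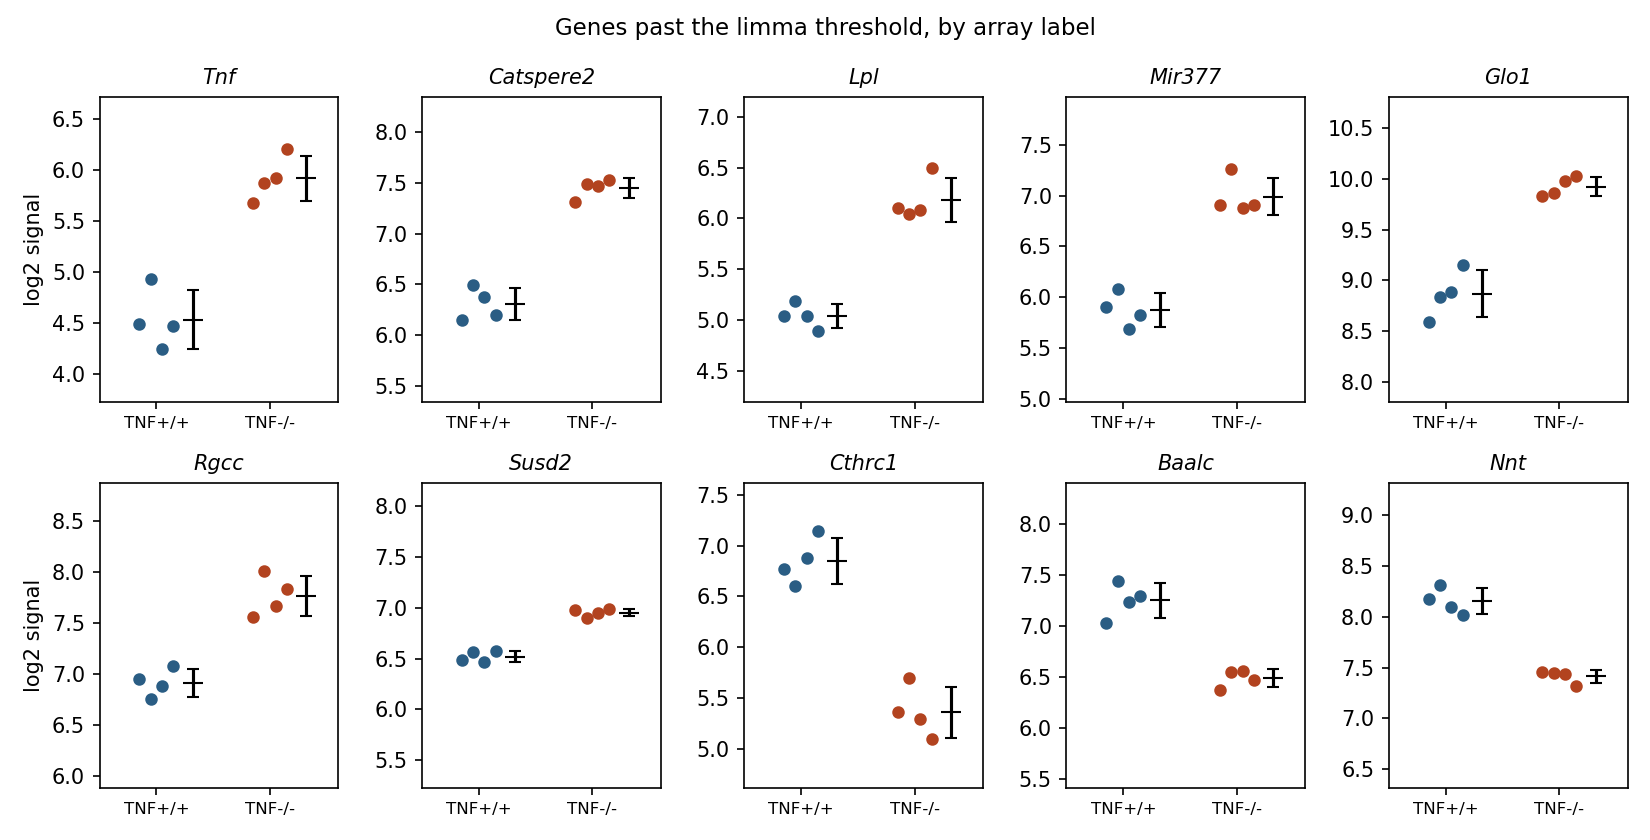
Log2 signal of the 10 named genes past the limma threshold, in the 4 arrays labelled TNF+/+ (blue) and the 4 labelled TNF-/- (orange), with the mean and SD of each group beside its points; every panel spans 3 log2 units. Tnf is higher in the arrays labelled TNF-/- (5.92 against 4.53).

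Over all probe sets, limma called 29 at an adjusted p under 0.05, of which 13 were higher and 16 lower in the arrays labelled TNF-/-. Of the 29, 12 pair with 1 gene symbol (11 genes), 8 with several, which are not named, and 9 are not listed in the platform annotation, so it is not known whether they measure genes or are controls; the largest change of the 29, -2.13, is among these 9. Of the 16 lower, 5 pair with only 2 sets of symbols (3 with one and 2 with the other), so they are not separate findings, and 2 of the 5 have identical values in all 8 arrays, which leaves 28 distinct among the 29. Significance Analysis of Microarrays (SAM), the test the study's design names, called 53 probe sets at an estimated false discovery rate of 4.49%, 32 higher and 21 lower, among them all 29 of limma. The SAM split depended on the setting: 14 higher and 23 lower after quantile normalization, 64 and 15 when dim probe sets were left out, and 234 and 27 when only probe sets with 1 gene symbol were tested. At an unadjusted p under 0.05, 3845 probe sets differed (2104 higher, 1741 lower). These counts rest on few arrays and on the setting. Limma called 1 probe set without TNF+/+ array 3, and none without TNF+/+ arrays 3 and 4 (3566 at an unadjusted p under 0.05, and 6 by SAM). With the replicate number as a block SAM called 8 and limma 0, so Tnf (limma, adjusted p = 0.129) and the other named genes did not pass. Limma called 63 (42 higher, 21 lower) when only probe sets with 1 gene symbol were tested.

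Genes beside Tnf on chromosome 17 were counted. Of the 50 measured genes nearest to Tnf in the gene order of GRCm38.p6, limma called 0, against 9 of 19805 genes elsewhere (Fisher's exact test, two-sided, p = 1), and SAM called 0; with so few calls elsewhere a count of 0 tells nothing. At an unadjusted p under 0.05 there were 7 of the 50, all lower in the arrays labelled TNF-/- (14% against 11.7% elsewhere; Fisher's exact p = 0.657). The lymphotoxin genes on either side differed by 0.00 ± 0.06 (SE) for Lta and 0.06 ± 0.07 for Ltb (limma, adjusted p = 0.988 and 0.805), with signals too low (3.65 to 3.89) to show much. Aif1, a gene of microglia that lies 3 measured genes away, differed by -0.14 ± 0.06 (limma, adjusted p = 0.445). Glo1 lies on the same chromosome, 150 measured genes from Tnf.

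**Figure D2:**
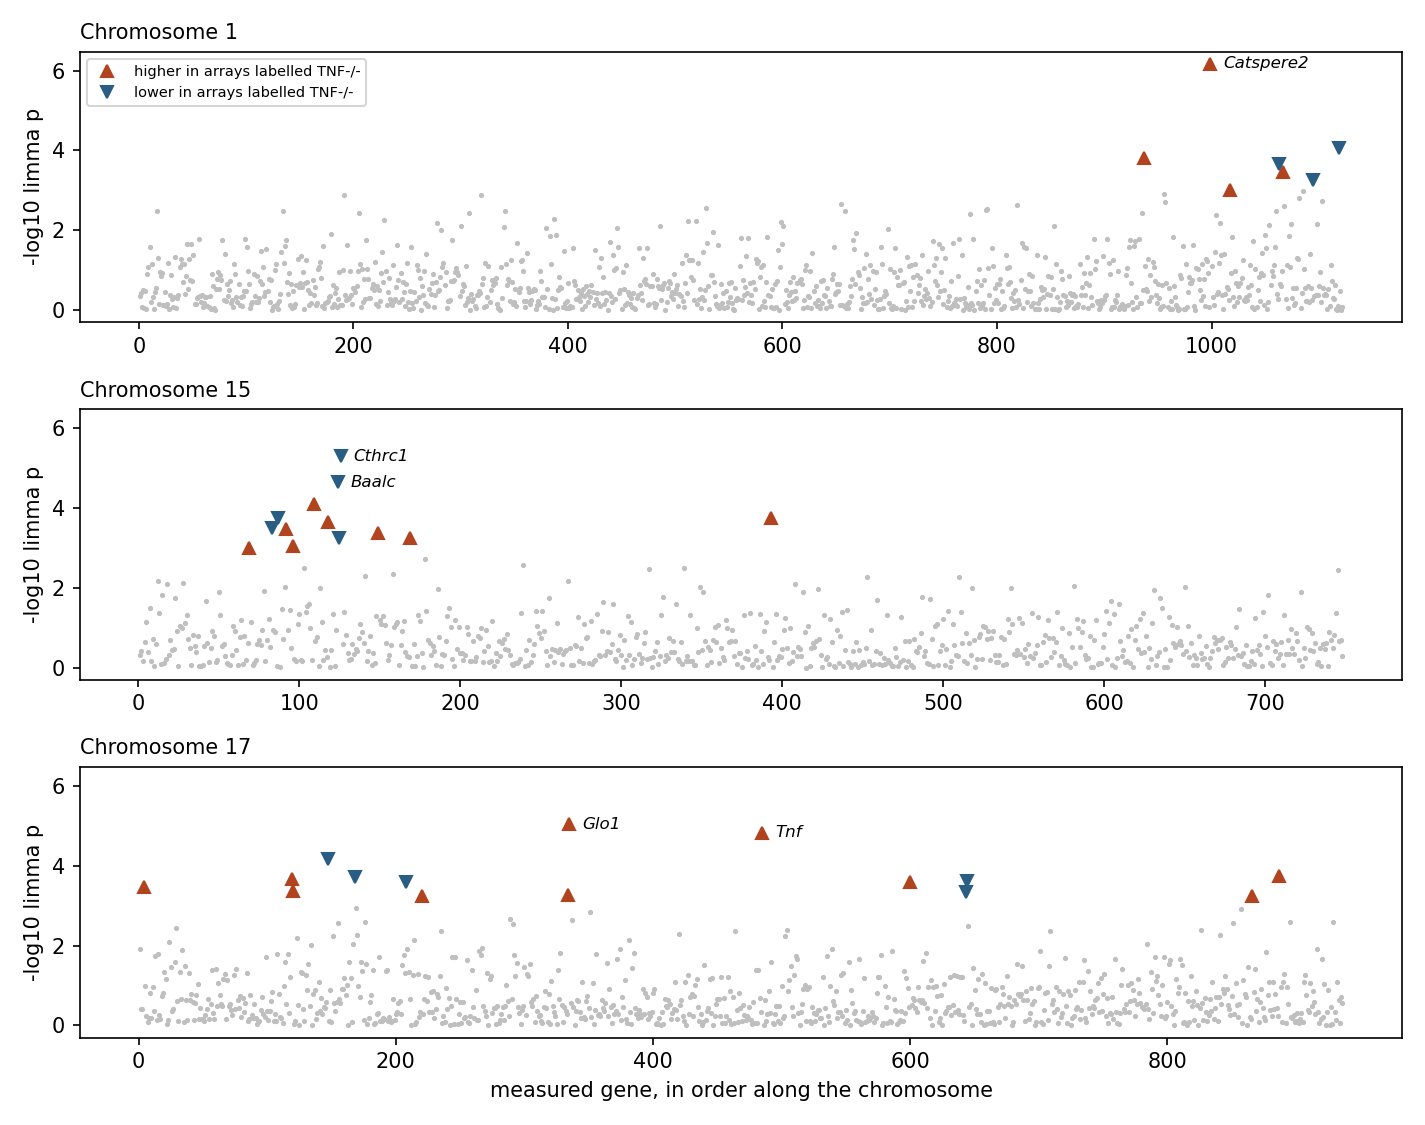
Limma p (-log10, unadjusted) of each measured gene against its rank in gene order along chromosomes 1, 15 and 17; triangles mark genes with p under 0.001, a threshold and a choice of chromosomes made after the values were seen. Chromosome 17 holds 15 marked genes among 936, chromosome 15 holds 13 among 748, and chromosome 1 holds 7 among 1122. The share on chromosome 1 (0.624% against 0.454% elsewhere) was not past the threshold (Fisher's exact test, adjusted p = 0.864).

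Signalling and immune genes were compared next. In the TNF pathway list, 0 of 23 measured receptors, adaptors and processing enzymes passed over all genes or adjusted over the list alone (camera, adjusted p = 0.774). The TNF receptor genes Tnfrsf1a and Tnfrsf1b differed by -0.05 ± 0.11 (SE) and -0.02 ± 0.07. Cytokine and other target genes of NF-kB, the transcription factor that TNF activates, gave 0 of 30 (camera, adjusted p = 0.277), with Nfkbia at -0.39 ± 0.17 (-0.24 without TNF+/+ array 3) and Icam1 at -0.18 ± 0.07 but Vcam1 at 0.27 ± 0.12. Interferon-stimulated genes fell as a list: 21 of 25 measured members were lower in the arrays labelled TNF-/-, with a median of -0.11 (camera, adjusted p = 0.00056; adjusted p = 0.134 with an estimated correlation). None of the 25 passed over all genes, and 3 fell when adjusted over the list alone: Oasl2 (-0.38 ± 0.08), Irf7 (-0.36 ± 0.07), which encodes a transcription factor of interferon responses, and Psmb9 (-0.24 ± 0.06). This list was not called when dim probe sets were left out (camera, adjusted p = 0.841). Antigen presentation genes gave 0 of 21 by either count (camera, adjusted p = 0.106).

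Among glial genes, those of mature oligodendrocytes and myelin fell as a list in the arrays labelled TNF-/-. Of 21 measured members 19 were lower, with a median of -0.22 (camera, adjusted p = 6.29e-06; adjusted p = 0.259 with an estimated correlation). None passed over all genes, and 5 fell when adjusted over the list alone. Of these, Trf, which encodes the iron carrier transferrin, stood at -0.56 ± 0.12 (SE), Cldn11, a tight junction gene of myelin, at -0.52 ± 0.14, Mag, which encodes myelin-associated glycoprotein, at -0.39 ± 0.09, Opalin at -0.38 ± 0.07 and Cnp at -0.32 ± 0.08. Mbp, which encodes myelin basic protein, differed by -0.09 ± 0.06 (-0.06 without TNF+/+ array 3). List means per array were 8.95, 8.98, 8.96 and 9.03 under the label TNF-/- and 9.05, 9.15, 9.20 and 9.26 under TNF+/+. The highest 2 are those of TNF+/+ arrays 3 and 4, and without these the difference of list means was -0.119 ± 0.0506 (SE) instead of -0.184 ± 0.0469. With all arrays the exact permutation p was 0.0286 unadjusted, the smallest that 4 against 4 can give, and 0.135 adjusted over the lists. Oligodendrocyte precursor genes gave 0 of 14 by either count (camera, adjusted p = 0.958).

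Microglial markers, which bear on the study's question of cell composition, gave 0 of 29 over all genes or adjusted over the list alone (camera, adjusted p = 0.493). Fcer1g was at -0.40 ± 0.13 (SE), P2ry13 at 0.24 ± 0.08 and Cx3cr1, the fractalkine receptor gene, at -0.09 ± 0.06 (-0.06 without TNF+/+ array 4). Astrocyte genes gave 0 of 21 (camera, adjusted p = 0.958), and Gfap, the intermediate filament gene of astrocytes, was at -0.34 ± 0.12 (limma, adjusted p = 0.381).

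Neuronal genes showed no list past the threshold. Genes common to most neurons gave 0 of 23 by either count (camera, adjusted p = 0.267), with Rbfox3, which encodes the nuclear protein NeuN, at -0.02 ± 0.07 (SE). Genes of excitatory neurons gave 0 of 20 (camera, adjusted p = 0.232). Genes of inhibitory neurons gave 0 of 21 over all genes and 2 adjusted over the list alone, both higher in the arrays labelled TNF-/- (camera, adjusted p = 0.232): Gad2, an enzyme gene of GABA synthesis, at 0.32 ± 0.06, and Dlx5 at 0.28 ± 0.07. The neurogenesis list gave 0 of 29 by either count (camera, adjusted p = 0.607). Within it Hes1 was at 0.32 ± 0.10, Sox2 at 0.26 ± 0.08 and Igfbpl1 at -0.35 ± 0.11, and Dcx, a marker of young neurons, was at -0.00 ± 0.13.

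Genes of monoamine synthesis, transport and reception gave 0 of 36 by either count (camera, adjusted p = 0.499). The serotonin synthesis gene Tph2 differed by 0.75 ± 0.65 (SE) and the serotonin transporter gene Slc6a4 by 0.56 ± 0.38, with an SD of 1.30 and 0.79 among the 4 arrays labelled TNF-/-. Without TNF-/- array 1, whose Tph2 signal was 4.02, they were 1.37 and 0.92, and without TNF-/- array 4 0.42 and 0.29; Tph2 was also 0.49 without TNF-/- array 3, 0.45 without TNF+/+ array 1 and 1.12 without TNF+/+ array 3. In both groups array 1 had the lowest signal of Tph2 (4.02 under TNF-/- and 4.27 under TNF+/+) and of Slc6a4 (4.68 and 4.76). No cause of this was tested. Slc18a2, the vesicular monoamine transporter gene, was at 0.62 ± 0.19, Htr1a at 0.35 ± 0.08 and Th, the tyrosine hydroxylase gene, at 0.09 ± 0.19, or -0.05 without TNF-/- array 3 (limma, adjusted p = 0.336, 0.23 and 0.888 with all arrays).

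Vascular genes and those of the brain's coverings followed. Blood-brain barrier genes gave 0 of 29 over all genes and 1 adjusted over the list alone, Slc7a5, a transporter gene for large neutral amino acids, at -0.44 ± 0.09 (SE) (camera, adjusted p = 0.224). The tight junction gene Cldn5 was at -0.15 ± 0.16, at 0.01 without TNF+/+ array 4 and at -0.28 without TNF+/+ array 2. Pericyte and smooth muscle genes gave 0 of 15 by either count (camera, adjusted p = 0.238). Meningeal fibroblast genes rose as a list in the arrays labelled TNF-/-, with 16 of 17 members higher and a median of 0.18 (camera, adjusted p = 0.000139; adjusted p = 0.375 with an estimated correlation). None of the 17 passed over all genes and 5 rose when adjusted over the list alone, among them Slc6a20a (0.41 ± 0.09), Slc6a13 (0.33 ± 0.10) and Lum (0.21 ± 0.06). List means per array were 6.51, 6.50, 6.52 and 6.44 under the label TNF-/- and 6.21, 6.23, 6.40 and 6.43 under TNF+/+, so most of the difference comes from TNF+/+ arrays 1 and 2, which also had the lowest means of the choroid plexus list (5.41 and 5.49) and the ependyma list (4.36 and 4.41). The meningeal list was not called by fry (adjusted p = 0.0983). Blood cell genes fell as a list, with 13 of 15 lower and a median of -0.08 (camera, adjusted p = 0.0144; adjusted p = 0.257 with an estimated correlation), and 0 of 15 passed by either count. The blood list's means (3.75 to 3.91 per array) lay below each array's 25th percentile of signal, which itself was 3.95 to 3.97 in the arrays labelled TNF-/- and 4.00 to 4.04 in the others. After quantile normalization the list had an adjusted p of 0.146.

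Neurotrophic factor genes rose as a list in the arrays labelled TNF-/-, with 12 of 16 higher and a median of 0.07 (camera, adjusted p = 0.0346; adjusted p = 0.259 with an estimated correlation). None passed over all genes and 1 adjusted over the list alone, Ret, which encodes a receptor for the GDNF family, at 0.27 ± 0.07 (SE). Igf1 was at 0.33 ± 0.11, and Bdnf, the brain-derived neurotrophic factor gene, at -0.04 ± 0.07. The list was not called without TNF-/- array 1 (camera, adjusted p = 0.155), TNF+/+ array 2 (0.0601) or TNF+/+ array 4 (0.097), nor when dim probe sets were left out (0.287). Its member Igf2 (0.24 ± 0.11) also belongs to the meningeal list, which rose in the same arrays. Nuclear genes of the respiratory chain fell as a list, with 29 of 35 lower and a median of -0.05 (camera, adjusted p = 0.0312; adjusted p = 0.656 with an estimated correlation), and 0 of 35 passed by either count. Cox5a was at -0.40 ± 0.15 and Cox6c at -0.24 ± 0.06. This list's means were highest in TNF+/+ arrays 3 and 4 (9.57 and 9.69), and without these arrays its direction was opposite (camera, adjusted p = 0.647). It was not called by fry (adjusted p = 0.538), nor without any 1 of TNF-/- arrays 1 and 2 and TNF+/+ arrays 3 and 4 (camera, adjusted p = 0.0563 to 0.425). Cytosolic ribosomal protein genes gave 0 of 26 (camera, adjusted p = 0.0725). Among the 35 splits of the 8 arrays into 4 and 4, 8, the real one included, gave 6 or more called lists.

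**Figure D3:**
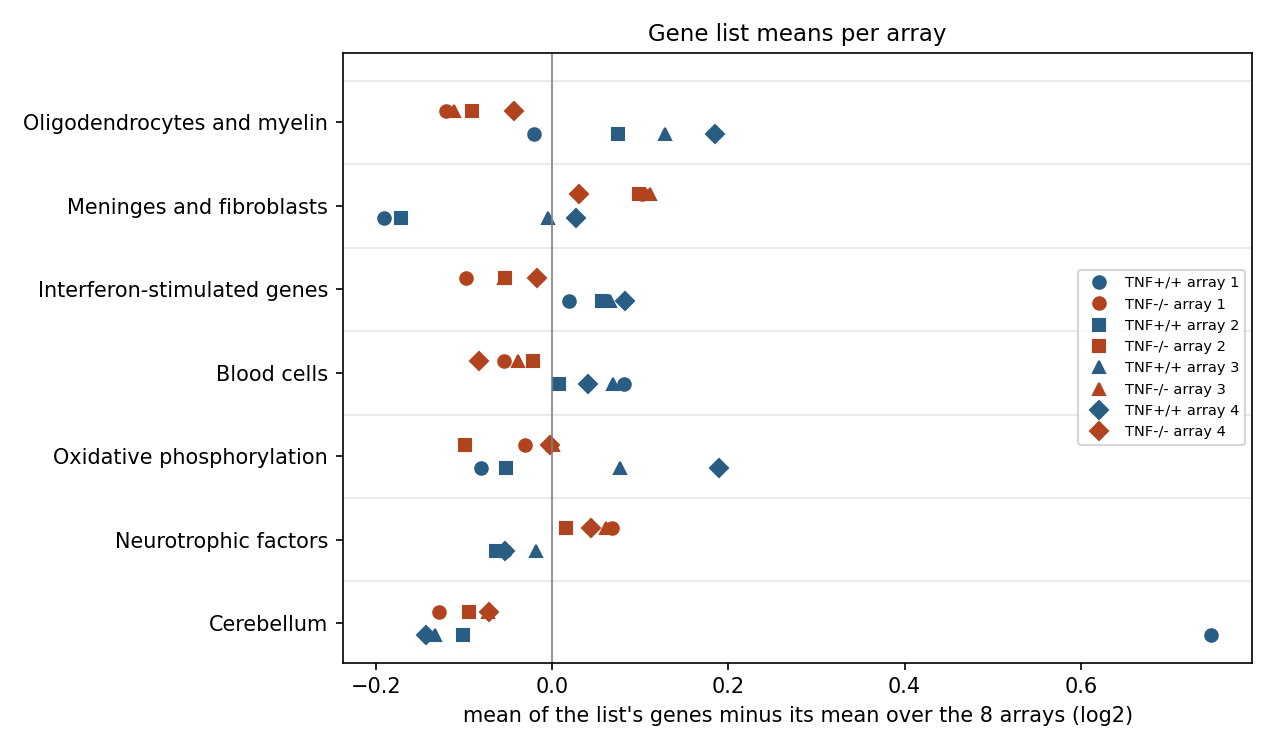
Mean log2 signal of each list's genes per array, minus that list's mean over the 8 arrays, for the 6 lists past the camera threshold and for the cerebellum list; blue stands for the label TNF+/+, orange for TNF-/-, and the marker shape for the replicate number. The myelin, interferon and blood means are lower in each array labelled TNF-/- than in each labelled TNF+/+, and the cerebellum mean of TNF+/+ array 1 stands alone.

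Strain-variable genes, a list of genes known to differ between C57BL/6 substrains or between C57BL/6 and a strain often used for gene targeting, moved in both directions. Of 16 measured members 2 passed over all probe sets, Glo1 (1.05) and Nnt (-0.74), and 5 adjusted over the list alone, the others being Trim12a (-0.74 ± 0.10, SE), Entpd4 (0.45 ± 0.11) and Wdfy1 (-0.44 ± 0.14). Elsewhere 8 of 19922 genes passed (Fisher's exact test, two-sided, p = 2.71e-05, a test chosen after the values were seen). The list did not move one way (camera, adjusted p = 0.958).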

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

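The tests of explanations in this part were chosen after the results were seen; the gene lists they use were fixed before. A single array stood apart from the other 3 of its group in 14 of 306 groups of 4 tested, and chance gives about 15. In arrays labelled TNF-/- these were Lpl in array 4 (6.50), Mir377 in array 2 (7.26), Nnt in array 4 (7.32), Tnfrsf1a (5.75), Trf (9.91) and Tshb (3.88) in array 3, and the list means of the TNF pathway in array 3 (5.79) and of meningeal fibroblasts (6.44) and striatum (7.91) in array 4. In arrays labelled TNF+/+ these were Map3k7 (7.92) and Slc18a2 (6.46) in array 3, Dnah6 in array 2 (4.75), Itpka in array 4 (8.02) and the cerebellum list mean in array 1 (6.49).

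Tnf signal was higher in the arrays labelled TNF-/-. A single exchanged label is argued against by a gap of 0.74 between the lowest array labelled TNF-/- and the highest labelled TNF+/+, above the pooled SD of 0.256. A rise of the whole region is argued against by the 13 of the 50 nearest genes that are brighter than the median gene, which differed by a median of -0.11 (SD over genes 0.12), with the highest at 0.06. An exchange of the labels of both groups as a whole cannot be told apart from transcription of what remains of the targeted gene, since either gives the difference of 1.39 in the single probe set. Transcripts of a modified allele that the probes still match are a candidate explanation that was not tested.

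Genes with a low p lay close together along chromosomes: the 92 genes with p under 0.001 made 86 pairs within 50 measured genes of each other, against a mean of 20.5 and a highest of 41 in 10000 random draws. Chromosome 17 held 15 of them among 936 genes (1.6% against 0.407% elsewhere; Fisher's exact test, adjusted p = 0.000398) and chromosome 15 held 13 among 748 (adjusted p = 0.000398). The 15 include Tnf itself, and none of the others lay within 50 measured genes of it. Ordinary co-variation of neighbours is argued against by the highest of the other 34 splits of the arrays, 32 pairs, yet 1 in 35 cannot exclude chance. Without TNF+/+ array 1, 68 pairs were left, above the highest random draw, which argues against cerebellar tissue in that array as the whole account. No splits were made without that array, so the 68 have no such reference of their own. Of 16 strain-variable genes 3 had p under 0.001, against 89 of 19922 others (Fisher's exact p = 5.1e-05). Of these 3, Glo1 lies beside another gene with p under 0.001, but Nnt and Trim12a have none within 50 measured genes. That test therefore bears little on the neighbourhoods. Genome segments of another strain in one group stay a possible account of the pattern. An effect of the genotype itself on these neighbourhoods stays open, as does a difference in substrain, which the labels do not give.

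Myelin genes were lower in the arrays labelled TNF-/-. A bias of bright probe sets is argued against by random lists matched on mean signal: 0 percent of 10000 had a median as low as -0.22, and their 2.5th and 97.5th percentiles were -0.02 and 0.10. Cerebellar tissue in TNF+/+ array 1 is argued against by a difference of list means of -0.221 ± 0.0362 (SE) without it. Without TNF+/+ arrays 3 and 4, which stand apart, the difference was -0.119 ± 0.0506, smaller than the -0.184 with all arrays by over 1.5 times. Part of the difference may therefore come from these arrays. For TNF+/+ that standard error rests on arrays 1 and 2 alone (list means 9.05 and 9.15), so a limit of 2 standard errors decides nothing there. A difference in dissection, for which the labels give nothing, and a biological difference between genotypes both stay open.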

How the results depend on the processing

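The settings without TNF+/+ arrays 3 and 4 and with a block of numbers 1 and 2 against 3 and 4 were chosen after seeing the data; the others were planned. Of the 35 splits into 4 and 4, only the real one reached 29 limma calls (highest other 1). The same held for 53 SAM calls (highest other 9), yet 1 in 35 cannot exclude chance. But 8, the real one included, reached its 6 called lists (highest other 10), so chance cannot be excluded there. The limma count of 29 was 63 (42 higher, 21 lower) with only probe sets of 1 gene symbol and 53 by SAM. It was 0 with the replicate block (4025 at an unadjusted p under 0.05) and 0 without TNF+/+ arrays 3 and 4 (3566). Leaving out 1 array gave 1 to 20: under the label TNF-/- 9, 13, 16 and 8 without arrays 1 to 4, and under TNF+/+ 20, 18, 1 and 12. No cause of these changes was tested. The SAM count of 53 was 261 (234 higher, 27 lower) with only probe sets of 1 gene symbol, 8 with the replicate block, 6 without TNF+/+ arrays 3 and 4, 19 with the 90th percentile of false calls, 20 with s0 of 0, and 3 to 38 with 1 array left out: 20 without TNF-/- array 3, and 26, 24, 3 and 29 without TNF+/+ arrays 1 to 4. Other settings gave 27 to 39 limma and 37 to 79 SAM calls. Same-numbered arrays deviated together with r of 0.07, 0.11, 0.10 and 0.07, and with 1 of 4 over 0.1 the numbers were not taken to pair the arrays. But 6 of 8 arrays correlated best with their own number (2 over random matchings), and their mean r (0.0876) was the highest of 24 matchings (highest other 0.0628; checked after seeing the data), a hint from the data, not the design, of something shared.

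Tnf kept its direction in 18 of 18 settings and was past the threshold in 9. Its difference was 1.39 with the replicate block (adjusted p = 0.129), 1.21 without TNF+/+ arrays 3 and 4 (adjusted p = 0.216; range over all settings 0.00251 to 0.216), and 1.29 to 1.52 with 1 array left out. Each of the other 9 called genes kept its direction in all 18 settings, past the threshold in 4 (Rgcc) to 15 (Catspere2). Beside Tnf, 20 or 100 neighbours also held 0 calls, which tells nothing with 9 elsewhere. The scalings moved the median of all probe sets from -0.01 to -0.00 (quantile) and -0.03 (centring).

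The 6 called lists became 0 with an estimated correlation, with adjusted p of 0.259 (myelin), 0.375 (meninges), 0.134 (interferon), 0.257 (blood), 0.656 (respiratory chain) and 0.259 (neurotrophic), and 4 to 7 with 1 array left out. Myelin, meninges, interferon and blood stayed past the threshold with any 1 array left out. The respiratory chain list had 0.647 in the opposite direction without TNF+/+ arrays 3 and 4, 0.538 by fry and an unadjusted 0.429 by exact permutation. Its values ran from 0.00115 to 0.425 with 1 array left out, missing the threshold without TNF-/- arrays 1 and 2 (0.0563 and 0.128) and TNF+/+ arrays 3 and 4 (0.0704 and 0.425, one at a time). The neurotrophic list had 0.287 among the brighter probe sets, 0.107 without TNF+/+ arrays 3 and 4, and 0.0236 to 0.155 with 1 array left out. Interferon had 0.841 among the brighter probe sets, meninges 0.0983 by fry and blood 0.146 after quantile normalization. Of lists not called, ribosomal proteins had 0.00144 among the brighter probe sets, 0.00722 after quantile normalization, 0.0257 with the mean of all probe sets and 0.00047 to 0.405 with 1 array left out, past it without TNF-/- array 2 (0.0437) and TNF+/+ array 1 (0.00047). Choroid plexus had 0.0306 after quantile normalization, 0.00194 without TNF+/+ arrays 3 and 4 and 0.00073 to 0.238 with 1 array left out, past it without TNF-/- arrays 2 and 4 (0.0437 and 0.02) and TNF+/+ array 3 (0.00073). Cerebellum had 5.89e-05 without arrays 3 and 4 and 0.0168 to 0.455 with 1 array left out, past it without TNF+/+ array 3 (0.0191) and array 4 (0.0168). The blood-brain barrier and ependyma had 0.0306 after quantile normalization. Ependyma had 0.0373 without arrays 3 and 4 and thalamus 0.0458 by fry. By exact permutation both had 0.0286 unadjusted (0.135 adjusted). Direction was read only for lists past the threshold; 49 of 657 list values turned while past it in neither setting. Lists were not run on probe sets of 1 symbol, which they already use, nor SAM with trend, weights or the block chosen later.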

Other observations

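Gene lists of brain regions, choroid plexus, ependyma and pituitary, fixed before the data were examined, were compared for differences in tissue content between the groups, and none of these passed camera, unlike the meningeal list above. Choroid plexus had 11 of 18 members higher in the arrays labelled TNF-/- (adjusted p = 0.0706), with Clic6 and Kcnj13 each at 0.25 ± 0.07 (SE), and ependyma and cilia 13 of 18 (adjusted p = 0.115), with Rsph4a at 0.51 ± 0.12, the 1 member that passed when adjusted over the list alone, and Dnah6 at 0.40 ± 0.12. Thalamic genes had 10 of 17 higher (adjusted p = 0.115), and 3 of these passed when adjusted over the list alone: Amotl1 (0.28 ± 0.06), Rorb (0.25 ± 0.06) and Synpo2 (0.22 ± 0.05). Cerebellar genes had 15 of 22 lower (adjusted p = 0.115), beside the high cerebellar signal of TNF+/+ array 1. Hippocampal genes moved in both directions (adjusted p = 0.958), and 3 of 18 passed when adjusted over the list alone: Itpka (-0.55 ± 0.14), Bok (-0.34 ± 0.09) and Cabp7 (0.42 ± 0.10). So did 2 of 22 hypothalamic genes (adjusted p = 0.265), Hdc (0.47 ± 0.10) and Otp (-0.29 ± 0.05). Adjusted p was 0.232 for striatum, 0.958 for olfactory bulb and 0.155 for pituitary, and these, choroid plexus and cerebellum gave 0 by either count. Cdhr1, a gene of olfactory mitral cells, was at 0.96 ± 0.28.

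Genes that neuronal activity induces moved in both directions (camera, adjusted p = 0.291). Adjusted over the list alone, 3 of 22 passed: Jun was higher in the arrays labelled TNF-/- (0.47 ± 0.09, SE), and Npas4 (-0.49 ± 0.11) and Junb (-0.26 ± 0.06) were lower, while none passed over all genes. Circadian clock genes (camera, adjusted p = 0.266) and heat shock and stress genes (0.958) gave 0 by either count, with the metallothionein gene Mt2 at -0.68 ± 0.19. Median, mean and test differ in sign in 5 lists, namely the strain-variable, oligodendrocyte precursor, hippocampus, olfactory bulb and heat shock lists, each with an adjusted p of 0.958. Xist, the RNA of the inactive X chromosome, was low in both groups (3.78 ± 0.07 and 3.76 ± 0.12, SD, n = 4), and the labels name male mice.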
